A study of Rattus norvegicus with 6 samples.

How the data were processed

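The 6 samples were lumbar spinal cords of male rats at day 14, 3 sham and 3 CCI, each a separate animal per the labels. Per the labels' protocols, genomic DNA was extracted with a column kit and labelled with random primers, Cy5 for the IP and Cy3 for the input, with no dye swap. Per the file headers, the authors' scanner files came from Agilent Feature Extraction 11.0.1.1, with a ChIP protocol and an array design on genome build rn4. The deposited intensity values were processed signals that the software had background-subtracted, detrended and scaled by 1 linear factor per dye, per the file headers. Dim spots stood at a floor in these values. The deposited log10 ratio column equalled the ratio of the processed signals within 1e-04 for 82.6% to 94.7% of probes per array and was 0 for most of the rest, so ratios were recomputed from the processed intensity. The share at 0 was 17.4% on sham 1, 15.6% on CCI 3 and 13.6% on CCI 1, against 5.35% to 7.49% on the others. These probes stayed in the main test with recomputed ratios, so any noise they carry differs between arrays. The other columns used, per the file headers, were the median and background intensity and the outlier, saturation and background flags.

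The arrays carried 179525 spots, of which 6856 control spots were left out. For each probe, log2 of processed red over processed green was taken, spots with an outlier flag in either channel were set aside (656 probes on at least 1 array), and each array's median was subtracted, with no loess or quantile step. The files gave probe coordinates and no gene names. The list of gene names at hand was on another genome build, so coordinates were not converted and no gene is named. Probes less than 1000 bp apart on a chromosome formed a region, and regions with at least 3 probes were tested. The value of a region on an array was the mean of its probes not flagged on that array, so arrays could average different probes.

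Groups were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, CCI minus sham, with Benjamini-Hochberg adjustment and a threshold of 0.05. Single values per array were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The test was checked on simulated data: with 200 of 16023 regions shifted, it recovered 22% of shifts of 0.5 log2 units and 100% of shifts of 1, with 2 and 19 false calls. The 19 were 8.68% of the calls made, above the threshold of 0.05. Same-numbered sham and CCI animals were not treated as pairs.

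Before the data were examined, the design, the main alternatives and the naming rule were fixed. The rule names, per direction, up to 10 regions past the threshold with no overlap between groups, filled up by lowest unadjusted p among regions without overlap, given then as values and not as changes. It also passed over promoters with no gene symbol. Since no region had a symbol, that exception was dropped and regions were named by coordinates. The parts of the rule that name fixed genes and list members could not be applied. The 25 gene lists, the comparison of germline with housekeeping promoters and the classes by CpG content were planned and not run, since they need gene names or sequence. Sets by chromosome, by share of 45 nt probes and by tiling were used in place of the lists and were chosen after seeing the data. They were tested with camera (preset correlation 0.01) and fry. The alternatives were normexp background correction with an offset of 50, applied to the median signals since a mean signal was not used here, quantile, scale and loess normalization, a filter on dim input probes, replicate and slide blocks, trend and robust eBayes, array weights, the median of probes, a minimum of 1 probe, averages of 3 adjacent probes, an adjusted p under 0.10, and leaving out each array. With the filter, arrays were centred again on the probes kept. Centring on all probes was run as well, and the choice between the 2 was made after seeing the data. Removal of a trend on probe length (45 to 60 nt), the filter in both channels, input noise as a covariate, slide 1 alone and the IP channel alone were added after seeing the data.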

Results

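Lumbar spinal cord from 6 male rats was profiled 14 days after surgery, 3 after a sham operation and 3 after chronic constriction injury (CCI), in which loose ligatures around the sciatic nerve produce lasting neuropathic pain. Methylated DNA was immunoprecipitated from each cord (MeDIP) and hybridised with the same animal's input DNA to a promoter array, the immunoprecipitate (IP) in the red channel and the input in the green. Each array held 172669 probes, which fell into 16123 genomic regions, and 16023 regions had enough probes to be tested. The median tested region held 10 probes over 1665 bp. Between 122903 and 128085 probes per array were well above background in the IP channel. In the input channel that number ran from 62156 (sham 1) and 64063 (CCI 3) through 75955 (CCI 1), 97974 (sham 2) and 105217 (sham 3) to 119460 (CCI 2). With 3 arrays per group, their number limits the precision. Regions are named by their coordinates in rat genome build rn4, since gene names were not used here.

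The first comparison asked whether the IP/input ratio of promoter regions in the lumbar cord differed between CCI and sham rats. How well this ratio reads methylation on these arrays was not checked, since the planned comparison of germline with housekeeping promoters needs gene names. Ratios of neighbouring probes, 162 bp apart at the median, correlated at 0.114, and at 0.0410 with probe length removed. The counts below therefore concern the ratio and do not show whether promoter methylation stayed the same. No region passed the test: limma called 0 of 16023 regions at an adjusted p under 0.05, and the smallest adjusted p in limma was 1.00. At an unadjusted p under 0.05, limma gave 422 regions, 88 with a higher and 334 with a lower IP/input ratio in CCI, where chance alone gives 801 on average. The regions differed by -0.02 log2 units at the median, with 5th and 95th percentiles of -0.24 and 0.17. The 95% interval of a region's difference reached 0.28 log2 units to either side at the median. In 1146 regions (7.15%) the 3 sham and 3 CCI values did not overlap, against 10% by chance. When known shifts were added to the measured values of 200 regions, the limma test recovered 93.5% of shifts of 1 log2 unit and 0% of shifts of 0.5. In this 1 draw, shifts of 0.5 in 200 of 16023 regions thus did not pass the adjusted threshold, against 22% on simulated values. The shifts were added in full to the finished region means. A change that dim probes recorded only in part would move the mean less, and this was not simulated.

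The 20 regions named by the fixed rule, applied without its condition on gene symbols, are given as values, since none passed the main test. The 10 with lower ratios in CCI differed by 1.35-fold to 1.57-fold. The region with the lowest p was chr19:24753230-24754933 (10 probes), at 0.82 ± 0.02 log2 units (SD, n = 3) in sham and 0.26 ± 0.14 in CCI, a difference of -0.56 ± 0.12 (SE). Its unadjusted p in limma was 0.000475 and its adjusted p 1.00. On chromosome 12, the region at 23697146-23698141 (6 probes) stood at 0.91 ± 0.07 in sham and 0.28 ± 0.25 in CCI (SD, n = 3), a difference of -0.63. On chromosome 9, the region at 6007657-6009379 (6 probes) stood at 0.48 ± 0.15 in sham and -0.17 ± 0.30 in CCI (SD, n = 3), the widest gap of the 20 at -0.65. On the X chromosome, the region at 28514105-28515854 (8 probes) stood at 0.54 ± 0.08 in sham and 0.07 ± 0.12 in CCI (SD, n = 3), a difference of -0.47. The 10 with higher ratios in CCI differed by 1.26-fold to 1.39-fold. Among them, chr1:217015603-217017156 (9 probes) stood at -1.11 ± 0.05 in sham and -0.71 ± 0.02 in CCI (SD, n = 3), a difference of 0.41 ± 0.11 (SE). Its unadjusted p in limma was 0.00293 and its adjusted p 1.00. The unplaced region at 426940-428670 had all 11 of its probes well above background in the input and stood at -3.24 ± 0.07 in sham and -2.76 ± 0.22 in CCI (SD, n = 3), a difference of 0.48. The region chr18:16240587-16244084 also had all 9 of its probes well above background in the input, and stood at -3.46 ± 0.17 in sham and -3.01 ± 0.11 in CCI (SD, n = 3), a difference of 0.45. With scale normalization the difference fell to 0.28 in this region and to 0.31 in the unplaced one. Of the 10 regions with lower ratios, 9 had under 50% of their probes well above background in the input, as did 4 of the 10 with higher ratios. With normexp background correction, the differences of the 20 regions shrank to between 0.0837 and 0.357 of their size. That setting also took median signals and added an offset of 50, which narrows log ratios by construction, so the shrinkage is not due to background alone. The unplaced region and chr18:16240587-16244084, bright in the input, fell to 0.16 and 0.09. With the median of probes in place of the mean, the differences were 0.15 for the chromosome 1 region (217015603) and -0.15 for the X chromosome region, and with slide as a block they were -0.99 for the chromosome 9 region and 0.72 for the unplaced region. A replicate block with a trend on probe length removed was added after seeing the data. It called the chromosome 12 and chromosome 9 regions (limma adjusted p = 0.0366 and 0.0296). Removal of the trend without the block called 0 regions. In the blocked fit p followed the size of the difference alone over the 20 regions, so these calls do not rest on each region's own spread.

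**Figure D1:**
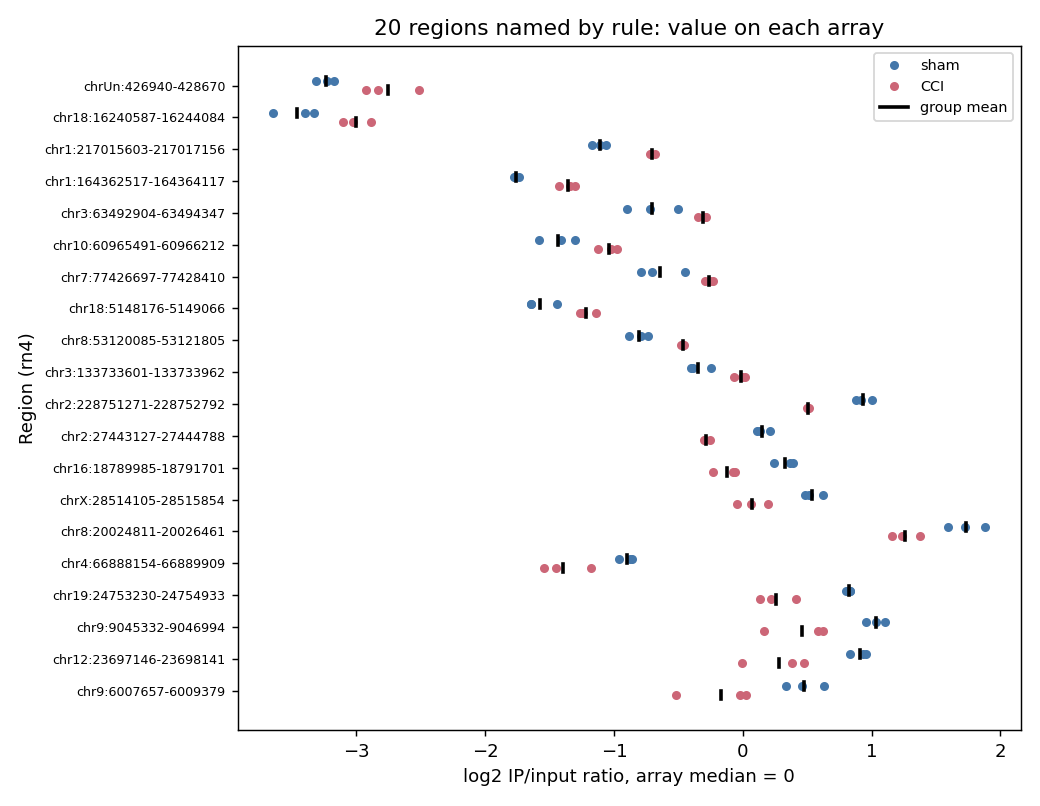
Log2 IP/input ratio (horizontal axis, array median at 0) of the 20 named regions (vertical axis, rn4 coordinates) on each of the 3 sham and 3 CCI arrays, with black bars at the group means. The points of the 2 groups do not overlap in any region, as the rule required, and none of the differences passed limma's main test.

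Slide and group were partly tied: slide 1 held the 3 sham arrays and CCI 3, and slide 2 held CCI 1 and CCI 2 alone. With slide as a block, the group difference comes from slide 1 alone, so from CCI 3 against the 3 sham arrays, and a fit within slide 1 gives the same differences by construction. In both fits limma called 0 regions, with 974 at an unadjusted p under 0.05 in the first and 775 in the second, where CCI 3 was assumed to vary like the sham arrays. Slide 2 held no sham array and gives no value. Without sham 1, limma called 0 regions and 897 reached an unadjusted p under 0.05. With array weights 979 did, 201 higher and 778 lower, and with normexp 743 did, 56 higher and 687 lower, with 0 called in both. The 979 is above the 801 that chance gives on average. In the main fit, though, divisions of the arrays 3 against 3 that cross the groups gave 335 to 2342, so a comparison with 801 decides nothing. The larger share of lower ratios was not kept under every scaling: with loess within arrays, 232 regions at an unadjusted p under 0.05 were higher and 180 lower, and with dim input probes left out, 136 were higher and 130 lower when arrays were centred on the probes kept, or 621 higher and 8 lower when they were centred on all probes.

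Single probes gave the same count. Of 172013 probes measured without an outlier flag on every array, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05, limma gave 5779 probes, 1761 higher and 4018 lower in CCI, where chance gives 8601 on average. The median probe differed by 0.01 log2 units.

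Chromosomes and classes of regions were compared next, as sets chosen after the values were seen. None of the 22 chromosomes (unplaced sequence counted as 1), the 3 classes of regions by their share of shortest probes, or the 89 regions tiled with at least 100 probes passed a test of a shift between CCI and sham. Camera asks whether the differences of a set depart from those of the other regions, and fry whether the set itself shifted. In every set call by camera, higher or lower in CCI thus means relative to the other regions. The camera test in limma called 0 of 26 sets with its preset correlation, 0 with an estimated correlation, and fry called 0. At an unadjusted p under 0.05 the 3 tests gave 1, 0 and 0 sets. The single set was the 4376 regions in which over 2/3 of probes had the shortest length of 45 nt, at 0.20 ± 0.05 in sham and 0.20 ± 0.06 in CCI (SD, n = 3). Its p in limma's camera was 0.0272 and its adjusted p 0.706, with an unadjusted p of 0.518 with an estimated correlation. Its own median differed by 0.002, while the classes with fewer 45 nt probes differed by -0.03 and -0.04. The camera p thus reflects the contrast with other regions. Chromosome 13 had a median ratio of -0.16 ± 0.03 in sham and -0.22 ± 0.03 in CCI (SD, n = 3; exact permutation p = 0.2, two-sided), the widest gap of any chromosome. On the X chromosome the median ratio was -0.05 ± 0.11 in sham and -0.10 ± 0.08 in CCI (SD, n = 3; exact permutation p = 0.6), and the arrays of both groups spread more widely there than on chromosome 13. With slide as a block, which leaves CCI 3 as the only CCI array in the difference, camera called 4 sets with its preset correlation (the X chromosome, the tiled regions and the class with few shortest probes lower in CCI, the class with many higher), each with an adjusted p of 0.313 or more with an estimated correlation. The fit within slide 1 holds the same differences and is no separate check.

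**Figure D2:**
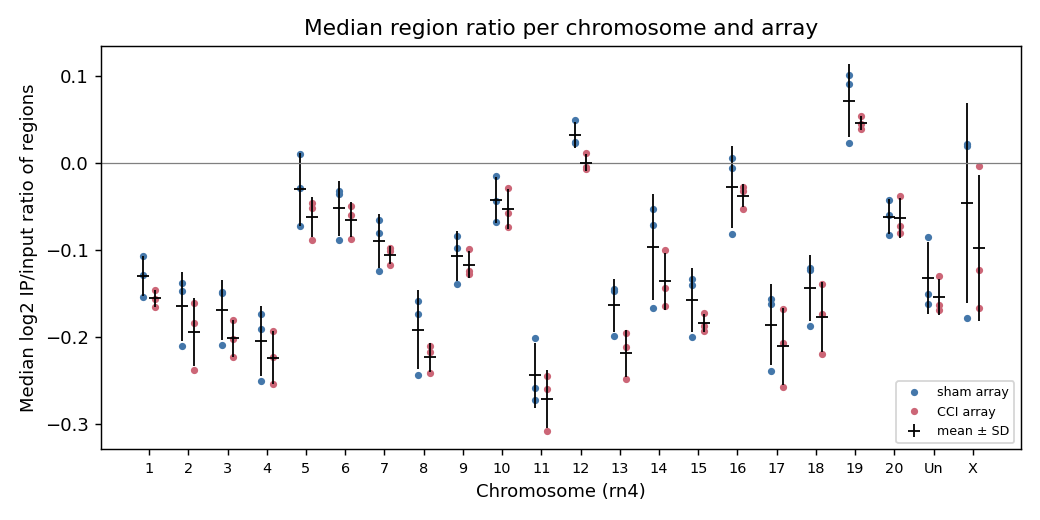
Median log2 IP/input ratio of the regions of each chromosome (rn4) on each sham and CCI array (points), with group means and SD (black, n = 3). The group medians differ by 0.06 or less on the log2 scale on every chromosome, and the X chromosome has the widest spread between arrays.

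The ratio varied far more between regions than between groups. In sham cords, the 10th and 90th percentiles of region values were -0.98 and 0.56 log2 units. Part of this range went with probe length: the median ratio in sham was 0.20 ± 0.05 (SD, n = 3) in the class of regions with over 2/3 of probes at 45 nt and -0.64 ± 0.06 in the class with under 1/3, and over all probes the ratio had a Spearman rho of -0.427 with length (probes are not independent replicates). Dimness went with length too: 60 nt probes were well above background in 21.7% of IP values and 12.8% of input values. At 45 nt these shares were 92.5% and 68.9%, so the gap between the classes cannot be told apart from dim values. Stretches of neighbouring regions far below the array median, chosen after the values were seen, were low in both groups. On chromosome 15, the 11 regions between 4980989 and 6289973 had a mean ratio of -5.07 ± 0.29 in sham and -5.12 ± 0.32 in CCI (SD, n = 3; exact permutation p = 0.8, two-sided). Their input signal was 4.25 log2 units above the array median and their IP signal -1.11 from it. In the stretches on chromosomes 5 and 1 given next, the input stood at 2.40 and 0.82 and the IP at -0.57 and -2.66. The stretches were thus not low in the same way. On chromosome 5, the 8 regions between 78091824 and 78823746 stood at -2.66 ± 0.27 in sham and -2.74 ± 0.16 in CCI (SD, n = 3; exact permutation p = 0.6). On chromosome 1, the 6 regions between 266512 and 1287460 stood at -3.21 ± 0.37 in sham and -3.23 ± 0.17 in CCI (SD, n = 3; exact permutation p = 1). Of the IP probe values in these stretches, 64.4% on chromosome 15, 79.1% on chromosome 5 and 29.5% on chromosome 1 were well above background, as were 100%, 98.0% and 72.6% of the input values, so ratios of probes dim in the IP alone are bounds and those dim in both channels give no bound. An exact test of 3 arrays against 3 cannot give a p below 0.1, and a low ratio set against other probes is not a methylation level.

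**Figure D3:**
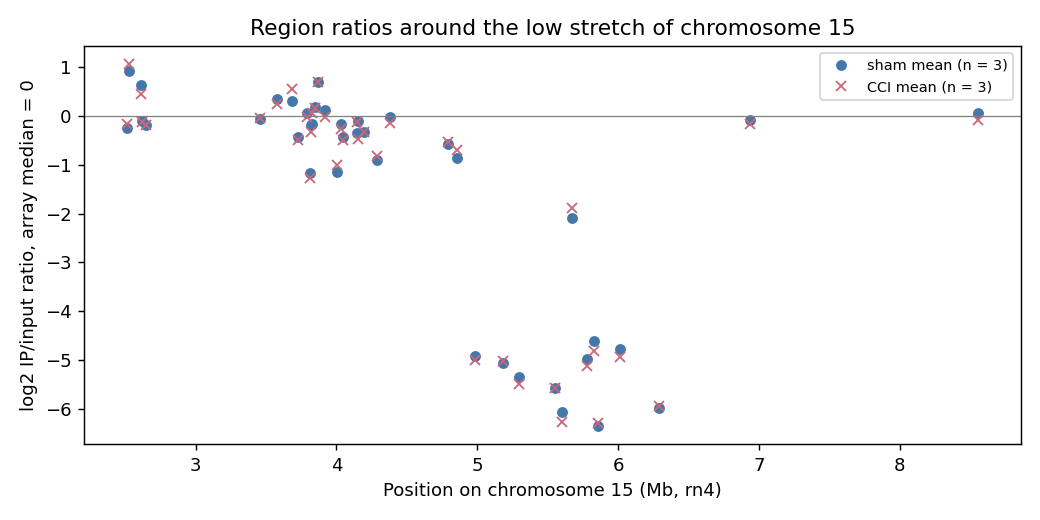
Mean log2 IP/input ratio (vertical axis, array median at 0) of regions along part of chromosome 15 (horizontal axis, Mb, rn4) in sham (circles, n = 3) and CCI (crosses, n = 3). The 11 regions of the low stretch lie between -2.08 and -6.35 in sham, with the CCI means beside them.

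The spread of ratios, which sets the scale of every difference, was compared between the groups as well. The interquartile range over regions was 0.813 ± 0.0107 in sham and 0.797 ± 0.0907 in CCI (SD, n = 3; exact permutation p = 0.8, two-sided, smallest possible 0.1). CCI 2 and CCI 3 had the narrowest and widest ranges, 0.723 and 0.899.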

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

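Probe length, both-channel filtering, the dim-probe filter centred on all probes, input noise, slide 1 alone, the IP channel alone and all region sets were chosen after seeing the data. The limma count stayed at 0 regions and 0 probes under every alternative fixed beforehand that was run, including each array left out (0 to 0). The unadjusted count of regions ran from 297 (without CCI 1) to 897 (without sham 1) when an array was left out. With input noise as a covariate, limma called 0 regions and 0 probes. At an unadjusted p under 0.05 that fit gave 632 regions, 156 higher and 476 lower in CCI, against 422 in the main fit. Correlations of same-numbered deviations ran from 0.00874 to 0.228, and those of other pairs from -0.332 to 0.189. In 1 of 3 sham arrays the best correlation was with its own number. With so few arrays these values neither show nor exclude a pairing by replicate number. The replicate block gave 0 regions, with 514 at an unadjusted p under 0.05. With the trend on probe length also removed, the replicate block gave 9 regions, 2 higher and 7 lower, among them the named regions on chromosome 12 (-0.60) and chromosome 9 (-0.62). These 9 had on average 0.167 to 2 input probes well above background, of 3 to 8. Without the block, removing the trend gave 0. The cause was not tested. The IP channel alone gave 1 region and 2 probes, or 0 regions and 2 probes with outlier spots kept. With slide as a block it gave 142 regions and 700 probes, or 96 and 778 with outlier spots kept, resting on CCI 3 as the only CCI array beside sham arrays. The region called in the IP channel alone, chr4:85755249-85756930, was 0.78 higher there and -0.14 in the ratio. Each array's mean leaves out its own flagged spots, so the 0.78 may compare unlike sets of probes. Region sets rose to 1 with normexp, 4 with slide as a block and 4 on slide 1, and ran from 0 to 3 without an array: 1 without sham 1, 1 without CCI 1, 3 without CCI 2 and 1 without CCI 3. The class with few 45 nt probes was lower in CCI without CCI 2 and higher without CCI 3, and every one of these set calls had an adjusted p of 0.313 or more with an estimated correlation. The difference in interquartile range, -0.02, ran from -0.0662 to 0.0215 without an array, turning positive without CCI 2. Of the 20 named differences, 5 fell below 2/3 of their size and 2 rose above 1.5 times with the median of probes, 1 and 3 with loess, 1 and 2 with slide as a block, 2 and 0 with scale normalization, and 5 of 7 fell so with bright input probes. The region chr2:27443127-27444788 turned to 0.00791 with dim input probes left out and arrays centred on all probes, a setting that moved the median difference of all regions to 0.11. The correction for GC content, the gene lists, the germline and CpG comparisons and a run without the 3 arrays of noisy input were not run.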

Other observations

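All tests in this part were chosen for patterns first seen in these values. A prediction was written before its test only for the bright input probes (whose second centring was added later) and for the differences across slides. The IP signal of a region was close between animals, with correlations over regions of 0.996 to 0.999 between arrays, while the input signal gave 0.950 to 0.972. Regions are not independent replicates. Among probes well above background in both channels, an array's deviation from the 6-array mean was 0.0582 to 0.0827 log2 units in the IP channel and 0.144 to 0.313 in the input channel. The X chromosome had less signal than the autosomes in the input, by -0.56 ± 0.06 log2 units (SD, n = 6). In the IP the gap was -0.265 ± 0.0133 in sham and -0.288 ± 0.00366 in CCI (SD, n = 3), with no overlap (exact permutation p = 0.1, the smallest possible). The ratio of the X chromosome shifted between arrays by -0.15 to 0.10 over all probes, and by -0.01 to 0.01 among probes well above background in the input.

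With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the count of called regions the real value was 0 and the highest other split gave 225. With a real count of 0 the comparison decides nothing. For probes the real value and the highest other were both 0, and for region sets they were 0 and 3.

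One split that crosses the groups, sham 1, CCI 1 and CCI 3 against the other three samples, called 225 regions in limma, with 2342 at an unadjusted p under 0.05, which points to a structure of the samples, and these were the arrays with the fewest input probes above background. With input probes well above background alone, that split called 0 percent of regions under either centring. At an unadjusted p under 0.05 it gave 3.02% of the 9515 regions then tested with arrays centred on those probes and 10.1% with arrays centred on all probes, against 14.6% of 16023 regions over all probes, while the split of sham 1, CCI 1 and CCI 2 against the rest called 299 or 131 there, so calls were possible. The split by slide, over all probes, called 0 regions, which argues against slide as the cause of the 225. Position stays open: of 2 positions used on both slides, 1 had its arrays on opposite sides and 1 on the same side. Input noise at dim probes may account for the 225 regions, and what lies behind the other split was not tested. That other split had CCI 1 and CCI 2, the only arrays on slide 2, on the same side. Slide thus stays open for it.

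Neighbouring probes, 162 bp apart at the median, agreed far less than animals did. Their IP signals correlated at 0.214, and at 0.0125 with probe length removed. Among probes well above background in both channels the latter was 0.00603, which argues against dim probes hiding an agreement. The IP/input ratios of neighbours, the measure used in the main test, correlated at 0.114, and at 0.0410 with probe length removed. Among probes well above background in both channels that second correlation was 0.0795. IP signal was lower for longer probes (Spearman rho -0.614 over probes), which argues against coordinates that do not belong to the spots. A candidate explanation is that each probe's own binding strength sets most of the IP signal. It would need the 0.0125 beside correlations of at least 0.991 between arrays, over the same probes with length removed. Those values are the pattern to be explained, so they are no separate test of it. No biological explanation was tested.

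In the IP channel alone, sham against CCI gave 1647 regions at an unadjusted p under 0.05 in limma, 1192 higher and 455 lower in CCI (the ratio leaned the other way), and 1 at an adjusted p under 0.05. This was 1 of the 10 splits with as many, the highest other gave 1019, which 10 splits are too few to judge, and the split by input noise gave 638, which decides nothing since the IP channel holds no input. Slide and injury are partly tied, and slide stays open: the split by slide (2 arrays against 4) gave 1607 regions and 6 at an adjusted p under 0.05 in limma, and the IP differences of CCI 1 and CCI 2 and of CCI 3 from separate sham arrays correlated at 0.0835 over regions (median of 3 divisions), or 0.122 with the sham arrays divided the other way. With slide as a block the IP channel gave 2708 regions, 2088 higher and 620 lower in CCI, and 142 at an adjusted p under 0.05, which goes against slide as the whole of the pattern but rests on CCI 3 alone, so it excludes nothing. Injury itself also stays open, as untested.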
